A study of Arabidopsis thaliana with 36 samples.

How the data were processed

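Roots and shoots of Arabidopsis thaliana seedlings of Col-0, hy5 and phyAB at 21 and 27 °C were sequenced in 36 libraries, 12 groups with n = 3. Per the labels, plants grew in long days (16/8h) with nights of 15 and 21 °C, were shifted on the third day after germination, and were harvested 6 days after germination. The series title states 18 h at the higher temperature, which conflicts with the 3 additional days of the treatment label, so the time at 27 °C is uncertain. Libraries came from a TruSeq Stranded mRNA kit and were read as single 50-base reads on a HiSeq2500. Per the submitters' processing notes, the authors used FastQC, TopHat2, HTSeq and edgeR with TAIR10, and gave no versions. The deposited files held integer read counts per gene made by the authors with HTSeq. The strand setting of the counting is not stated, so genes that overlap or lie antisense to others are uncertain.

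Each file held 32833 genes and 5 summary lines, which were set aside. Reads outside genes were 0.690 to 2.84% of all, ambiguous reads 0.104 to 0.321% and reads that mapped to several places 5.22 to 11.2%, all left uncounted by the authors. The last share was 5.22 to 6.12% in roots and 8.40 to 11.2% in shoots, and genes with near-identical copies may be undercounted. Median gene counts per library were 22383300 in roots and 21622400 in shoots, and 22632 to 23791 genes had reads. The 10 most abundant genes took 3.30 to 9.18% of the counts. Replicates differed by more than sampling (chi-square over degrees of freedom 2.66 to 10.3), so no library was a copy of another. The median biological coefficient of variation was 5.49% in roots and 6.69% in shoots.

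Counts were fitted with edgeR 4.0.16 in R 4.3.3 (TMM size factors, filterByExpr, robust quasi-likelihood F-tests). One fit per tissue held 18 libraries, 6 group means and 12 residual degrees of freedom, with 20550 genes in roots and 20574 in shoots. A joint fit of 36 libraries with 24 residual degrees of freedom and 21872 genes gave the difference between tissues. The 15 comparisons were the temperature effect in each genotype and tissue, its difference between each mutant and Col-0, the genotype effect averaged over both temperatures, and the difference of the Col-0 temperature effect between tissues. Benjamini-Hochberg adjusted p under 0.05 within a comparison counted as passing. Folds are log2, and CPM of single genes use TMM-scaled library sizes, while summed CPM use total gene counts.

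Gene lists were written from general knowledge before the data were examined: 22 lists with 496 genes, of which 483 were kept and 13 lacked a matching name. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, and again with the correlation estimated, adjusting over all 330 tests. Names came from a TAIR10.1 annotation, which matched 32548 of the genes and was used only for names and neighbours, since the files rest on TAIR10.

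The genes named were set by a rule made before the data were examined, as were the comparisons, the lists and all alternatives but 1. It took 9 genes always (HY5, HYH, PHYA, PHYB, PIF4, YUC8, IAA29, NRT2.1 and CHS). It added the genes past the threshold with the largest changes, 8 per direction for the Col-0 temperature and genotype effects and 3 for the others, with a mean CPM of at least 2. For temperature and genotype effects the 3 libraries of one group had to lie above the 3 of the other. It also added up to 4 members per list with the smallest adjusted p. Genes without a symbol among the largest changes, 1 to 13 per comparison, were mostly left out. The 13 seed genes were chosen after the largest changes in phyAB shoots had been seen.

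Alternatives were RLE size factors, no filter on low counts, DESeq2 1.42.0, a fit of only the groups compared, a replicate block, and leaving out each library in turn. Leaving out the phyAB root replicate 3 libraries, whose source label says shoot, was added after the files had been seen. The method was tested on simulated data made from these counts with added changes. At a log2 change of 1, 91.0% were recovered for the Col-0 root temperature effect, 80.6% for the hy5 root difference and 71.6% for the hy5 shoot difference. At 0.5 these shares were 68.7, 46.3 and 36.4%, with 9 of 179, 5 of 149 and 7 of 133 calls false. Splicing, alleles and strand were not analysed here, because the counts hold none of them.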

Results

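The data were gene counts of 36 libraries from seedlings of Arabidopsis thaliana in 12 groups, n = 3 each: roots and shoots of Col-0, hy5 and phyAB at 21 and 27 °C. Total gene counts ran from 18338700 to 26481900 per root library and from 17552300 to 25431700 per shoot library. The first principal component of the roots, with 41.9% of the variance, parted Col-0 from both mutants, and the second, with 29.3%, parted the temperatures. In shoots the first component, with 38.6%, parted the temperatures, and the second, with 22.8%, parted phyAB from the other genotypes. The labels do not say whether the replicates came from separate cultures, so every p-value measures only the spread between these samples. The value behind each plus-minus sign is a standard error beside a log2 fold change and a standard deviation beside counts scaled to library size (CPM).

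The mutant lines are named for HY5, a transcription factor of light signalling, and for PHYA and PHYB, which encode photoreceptors. In roots, HY5 stood at 16.8±1.92 CPM in hy5 against 48.2±0.879 CPM in Col-0 at 21 °C and at 15.4±0.989 against 52.0±2.53 CPM at 27 °C (-1.64±0.05, adjusted p = 5.81e-18, mean of both temperatures). In the shoot libraries labelled hy5 it stood at 24.8±1.24 CPM against 21.9±1.38 CPM in Col-0 at 21 °C, above the control, and at 8.95±1.55 against 18.0±2.31 CPM at 27 °C (-0.41±0.08, adjusted p = 0.000695). In phyAB, PHYA (-2.99±0.04, adjusted p = 1.76e-24) and PHYB (-1.26±0.04, adjusted p = 1.13e-18) were lower in roots, and PHYA (-3.19±0.07, adjusted p = 6.12e-17) and PHYB (-0.75±0.04, adjusted p = 2.57e-11) in shoots. Both phyAB tissues also held less HY5 (-1.37±0.05 in roots and -0.59±0.08 in shoots). The labels name no alleles, and because the HY5 transcript went against the label at 21 °C, every direction given for the shoot libraries labelled hy5 rests on that label.

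**Figure D1:**
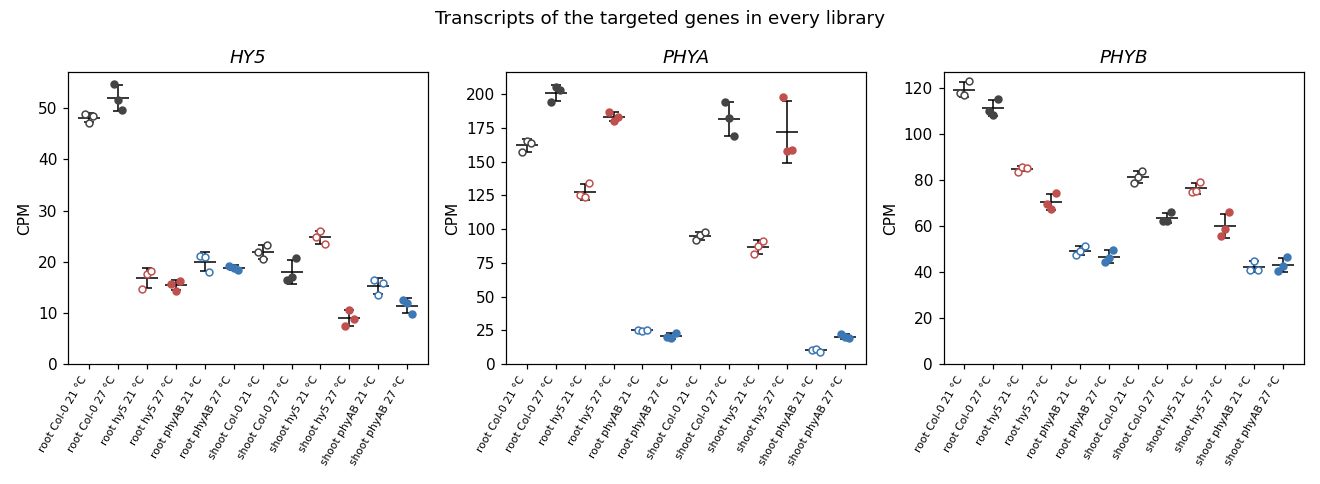
CPM of HY5, PHYA and PHYB (vertical axes, linear from 0) in each library of the 12 groups, with open points at 21 °C, filled points at 27 °C, dashes for means and bars for standard deviations (n = 3). HY5 averaged 16.8 CPM in hy5 roots and 24.8 CPM in the shoot libraries labelled hy5 at 21 °C, while PHYA averaged 25.1 CPM in phyAB roots against 162 CPM in Col-0 roots.

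In Col-0 roots, growth at 27 °C lowered transcripts of iron uptake and flavonoid synthesis. FRO2, the root ferric chelate reductase, fell to 23.2±4.69 against 556±75.3 CPM at 21 °C (-4.57±0.17, adjusted p = 5.09e-11, n = 3 per group). NRT2.1, a high-affinity nitrate transporter, fell from 4.48 to 0.132 CPM (-4.94±0.43, adjusted p = 1.99e-08). Among the genes that rose most were MRN1, which makes the triterpene marneral (4.21±0.38, adjusted p = 6.03e-07), and TPX2, a thioredoxin-dependent peroxidase whose reads may be shared with TPX1 (3.71±0.21, adjusted p = 7.05e-09). Of 20550 genes tested, 5456 rose and 5608 fell, 717 and 565 of them by 2-fold or more.

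The iron set was the most complete change in Col-0 roots. All 21 iron deficiency-induced genes tested fell (21 adjusted over the list alone), with a median of -2.13 (adjusted p = 2.88e-38, and 0.00619 with an estimated correlation). Alongside FRO2 they included CYP82C4 (-4.33±0.31, adjusted p = 1.06e-07) and F6'H1 (-2.00±0.07), which make the coumarins that mobilise iron, the regulators BHLH100 (-4.21±0.33, adjusted p = 1.25e-07), MYB72 (-4.17±0.75, adjusted p = 0.000148) and MYB10 (-2.96±0.15), and the transporter OPT3 (-2.10±0.10). MYB72 was scarce, at 0.0585±0.0506 against 1.2±0.268 CPM. BHLH100 fell to 1.46±0.913 against 25.9±2.74 CPM.

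Flavonoid synthesis fell in Col-0 roots in 10 of 11 genes (10 adjusted over the list alone; median -1.07, adjusted p = 2.24e-16, and 0.00541 with an estimated correlation). CHS, the entry enzyme chalcone synthase, fell to 457±17 against 967±12 CPM (-1.08±0.08, adjusted p = 2.01e-10). Other enzymes fell as well: CHI (-1.91±0.06, adjusted p = 5.58e-16), the flavonoid hydroxylase F3'H (-1.19±0.08), the flavonol synthase FLS1 (-1.09±0.07) and the ligase 4CL3 (-1.07±0.07). In contrast to the structural genes, their regulator HY5 did not pass (0.11±0.07, adjusted p = 0.158), while its relative HYH (-0.29±0.08, adjusted p = 0.00405) fell.

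Nitrate genes moved in both directions. Of 27 tested, 18 fell and 2 rose (20 adjusted over the list alone; median -0.49, adjusted p = 6.20e-06, but adjusted p = 0.419 with an estimated correlation). The nitrate reductase NIA1 (-2.83±0.15) and the glutamine synthetase GLN1;2 (-1.43±0.10) fell with NRT2.1, while NRT1.5, which loads nitrate into the xylem, rose to 1708±173 against 394±37.8 CPM (2.11±0.08, adjusted p = 8.60e-15). Root hair genes fell in 9 of 18 (9 adjusted over the list alone; median -0.37, adjusted p = 0.0332, but adjusted p = 0.769 with an estimated correlation), among them the wall protein gene PRP1 (-2.00±0.17) and the proton pump AHA7 (-0.92±0.14). Cell division genes fell in 23 of 33 (23 adjusted over the list alone; median -0.28, adjusted p = 0.000364, but adjusted p = 0.525 with an estimated correlation), each by little, such as the ribonucleotide reductase RNR1 (-0.40±0.04) and the kinesin HIK (-0.50±0.06). Cold-responsive genes fell in 7 of 13 with 1 rising (8 adjusted over the list alone; adjusted p = 0.00104, but adjusted p = 0.113 with an estimated correlation), including the galactinol synthase GOLS3 (-3.48±0.35) and KIN1 (-2.98±0.13), which is uncertain because its reads may be shared with its close copy KIN2.

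Evening clock genes rose in 8 of 10 (8 adjusted over the list alone; median 0.88, adjusted p = 6.20e-06, but adjusted p = 0.0863 with an estimated correlation): the evening complex members BOA (1.72±0.10), LUX (1.58±0.10) and ELF4 (1.44±0.11). Morning genes fell in 8 of 15 with a median of -1.51, including PRR7 (-3.02±0.55) and CDF1 (-2.27±0.28), but the list test did not pass (adjusted p = 0.121). Root-specific markers rose in 7 of 21 and fell in 1 (8 adjusted over the list alone; median 0.18, adjusted p = 0.00197, but adjusted p = 0.344 with an estimated correlation), with the aquaporin TIP2;3 (1.91±0.09) and the Casparian strip gene CASP5 (2.67±0.15), whose reads may be shared with its relatives. Touch and wound genes rose in 9 of 17 (10 adjusted over the list alone; adjusted p = 0.0133, but adjusted p = 0.569 with an estimated correlation), such as the ethylene response factors ERF6 (1.15±0.10) and ERF5 (1.02±0.10). Photosynthesis genes rose in 14 of 31 (14 adjusted over the list alone; median 0.50, adjusted p = 0.0258, but adjusted p = 0.790 with an estimated correlation), led by PSBO2 (1.58±0.08) of photosystem II. They were traces in roots: their summed CPM was 343±62.9 at 21 °C and 545±28.8 at 27 °C, against 110329 CPM in Col-0 shoots at 21 °C.

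The other lists did not pass in Col-0 roots. Heat shock genes split, with 11 of 28 rising and 10 falling (23 adjusted over the list alone; adjusted p = 0.653): the chaperone HSP90.1 (1.25±0.09) and the heat regulator DREB2A (1.68±0.10) rose and HSP90.2 (-0.76±0.06) fell. Auxin response rose in 6 and fell in 2 of 22 (7 adjusted over the list alone; adjusted p = 0.372). Auxin synthesis and transport rose in 3 and fell in 3 of 17 (6 adjusted over the list alone; adjusted p = 0.843), with the tryptophan aminotransferase TAR2 (-0.80±0.12) lower. PIF and shade genes rose in 5 and fell in 4 of 20 (9 adjusted over the list alone; adjusted p = 0.555). Their median was 0.09 and their mean -0.09, and the test pointed up. Light signalling genes rose in 8 and fell in 7 of 26 (15 adjusted over the list alone; adjusted p = 0.712). Their median was 0.01 and their mean -0.28, and the test pointed down. The stress protein ELIP1 (-3.17±0.14) and the transcription factor HFR1 (1.11±0.10) stood at its ends. Cell wall loosening genes fell in 11 and rose in 2 of 24 (13 adjusted over the list alone; adjusted p = 0.0598), with opposite changes in the wall enzymes XTH20 (-2.90±0.12) and XTH24 (2.70±0.12). Phosphate starvation genes fell in 6 and rose in 3 of 18 (9 adjusted over the list alone; adjusted p = 0.194), such as the phospholipase NPC4 (-2.46±0.13). Of the auxin markers, IAA29 (1.02±0.33, adjusted p = 0.0111) rose and the auxin synthesis enzyme YUC8 did not pass (0.07±0.12, adjusted p = 0.644).

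Smaller counts came from the remaining lists. Salicylic acid defence rose in 5 of 16 (5 adjusted over the list alone; adjusted p = 0.357) and included the regulator WRKY70 (2.24±0.25). Jasmonate response rose in 5 and fell in 3 of 15 (8 adjusted over the list alone; adjusted p = 0.459), with the regulator MYC2 (0.85±0.06) higher. Chlorophyll synthesis rose in 6 and fell in 3 of 17 (9 adjusted over the list alone; adjusted p = 0.149), with the methyltransferase CHLM (1.04±0.08) higher. Brassinosteroid synthesis rose in 5 and fell in 2 of 9 (7 adjusted over the list alone; adjusted p = 0.638), with the steroid hydroxylase CPD (0.32±0.07) slightly higher. Other single genes with large changes were the linker histone HIS1-3 (3.40±0.20), the branched-chain aminotransferase BCAT-2 (3.39±0.24) and the trehalose phosphatase TPPJ (-4.15±0.27). PHYA rose (0.31±0.05, adjusted p = 1.39e-05) and PHYB did not pass (-0.10±0.05, adjusted p = 0.0807).

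In Col-0 shoots, 27 °C lowered flavonoid synthesis far more than in roots, lowered transcripts of the light-stress proteins ELIP1 and ELIP2, and raised SEN1 and DYL1. CHS fell to 57.3±3.97 against 964±53.3 CPM (-4.07±0.08, adjusted p = 2.69e-18, n = 3 per group). The chloroplast protein ELIP1 (-6.58±0.47, adjusted p = 5.35e-08) fell to 1.64±0.634 against 159±39.3 CPM. SEN1, a gene induced in darkness, rose to 231±28.7 against 15.1±2.71 CPM (3.93±0.38, adjusted p = 1.16e-06), and DYL1, a dormancy-associated gene, to 127±20 against 11.2±1.07 CPM (3.5±0.26, adjusted p = 7.65e-08). Of 20574 genes tested, 6371 rose and 5712 fell, 1022 and 1154 of them by 2-fold or more.

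Flavonoid and anthocyanin genes fell in 18 of 20 (18 adjusted over the list alone; median -3.55, adjusted p = 2.32e-40, and 0.00402 with an estimated correlation). Among the deepest were anthocyanin steps: the transferase TT19 (-5.06±0.22, adjusted p = 5.20e-11), the glycosyltransferase UGT79B1 (-4.98±0.44, adjusted p = 3.83e-07), the reductase DFR (-4.86±0.32, adjusted p = 2.18e-08) and the dioxygenase LDOX (-4.45±0.29, adjusted p = 1.53e-08). FLS1 (-3.46±0.08), UGT78D1 (-2.54±0.07) and CHI (-2.54±0.07) fell too. HY5 fell slightly (-0.28±0.11, adjusted p = 0.0347), HYH more (-0.98±0.22, adjusted p = 0.00155), and ELIP2 (-5.02±0.32) fell with ELIP1.

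Photosynthesis genes fell in 24 of 33 (28 adjusted over the list alone; median -0.36, adjusted p = 3.95e-05, but adjusted p = 0.556 with an estimated correlation): the ferredoxin FD2 (-1.27±0.07), the Calvin cycle kinase PRK (-0.84±0.05) and the Rubisco subunit RBCS2B (-1.03±0.07), whose reads may be shared with its copies. Chlorophyll synthesis fell in 14 of 17 (15 adjusted over the list alone; median -0.61, adjusted p = 1.84e-06, but adjusted p = 0.186 with an estimated correlation), including the reductase PORC (-1.39±0.06), the aminomutase GSA1 (-0.80±0.04) and the chelatase subunit CHLI1 (-0.79±0.05). Heat shock genes fell in 13 and rose in 9 of 29 (22 adjusted over the list alone; median -0.53, adjusted p = 0.0258, but adjusted p = 0.419 with an estimated correlation), with the chaperones HSP90.2 (-1.32±0.07), CLPB3 (-1.07±0.07) and HSP60 (-1.04±0.06) all lower. Cold-responsive genes fell in 11 of 15 (12 adjusted over the list alone; median -1.08, adjusted p = 0.000225, but adjusted p = 0.112 with an estimated correlation), such as the starch amylase BAM3 (-1.15±0.07), the membrane protein COR413PM1 (-1.04±0.07) and KIN2 (-2.88±0.20), whose reads may be shared with KIN1.

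Evening clock genes rose in 8 of 10 (9 adjusted over the list alone; median 0.94, adjusted p = 0.00161, but adjusted p = 0.419 with an estimated correlation), among them COR27 (3.25±0.25), BOA (2.42±0.15), ELF4 (2.13±0.26) and TOC1 (0.64±0.06). Morning genes fell in 12 of 14 with a median of -1.57, without a list call (adjusted p = 0.213). PIF4, which drives warm-temperature elongation, rose from 0.0495 to 1.75±0.210 CPM (4.99±0.48, adjusted p = 9.12e-09), a level of few reads. Its usual targets did not follow as a group: PIF and shade genes rose in 6 and fell in 4 of 24 (9 adjusted over the list alone; adjusted p = 0.777), IAA29 (0.76±0.32, adjusted p = 0.0474) rose and YUC8 did not pass (-0.41±0.18, adjusted p = 0.0514). PHYA rose (0.94±0.08, adjusted p = 7.12e-09), PHYB fell (-0.36±0.06, adjusted p = 3.40e-05) and NRT2.1 fell (-4.07±0.35, adjusted p = 1.83e-09). TPX2 (3.73±0.75, adjusted p = 0.000775) and the scarce vacuolar channel BETA-TIP (3.78±0.77, adjusted p = 0.000425) rose, and the defence gene PCC1 (-4.92±1.52, adjusted p = 0.0139) fell.

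Hormone lists did not pass in Col-0 shoots. Auxin response fell in 7 and rose in 3 of 26 (9 adjusted over the list alone; adjusted p = 0.650). Their median was 0.07 and their mean -0.05, and the test pointed down. The repressor IAA17 (-1.01±0.08) and the ethylene synthesis gene ACS4 (-3.27±0.40) fell. Auxin synthesis and transport rose in 4 and fell in 6 of 17 (11 adjusted over the list alone; adjusted p = 0.879), with the exporter ABCB19 (0.73±0.05) higher. Brassinosteroid synthesis rose in 6 and fell in 1 of 9 (7 adjusted over the list alone; adjusted p = 0.172), with the oxidases BR6OX1 (2.49±0.32) and BR6OX2 (-1.03±0.11) in opposite directions. Jasmonate response fell in 9 and rose in 3 of 18 (12 adjusted over the list alone; adjusted p = 0.186), with the synthesis enzymes AOC2 (-2.72±0.21) and LOX2 (-2.65±0.32) lower. Salicylic acid defence fell in 1 and rose in 0 of 16 (1 adjusted over the list alone; adjusted p = 0.850). Touch genes rose in 5 and fell in 2 of 17 (7 adjusted over the list alone; adjusted p = 0.597), with ERF6 (2.62±0.36) higher.

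Growth and nutrient lists did not pass either. Cell wall loosening fell in 12 and rose in 4 of 26 (16 adjusted over the list alone; adjusted p = 0.0715). Cell division fell in 9 and rose in 4 of 33 (11 adjusted over the list alone; adjusted p = 0.858), with the cyclin CYCD3;1 (0.71±0.07) higher. Iron genes fell in 7 of 19 (8 adjusted over the list alone; median -0.49, adjusted p = 0.115), with the nicotianamine synthase NAS1 (-2.05±0.09) lower. Nitrate genes rose in 12 and fell in 10 of 26 (22 adjusted over the list alone; adjusted p = 0.944), with the kinase CIPK3 (1.62±0.06) higher. Phosphate genes fell in 6 and rose in 1 of 17 (7 adjusted over the list alone; adjusted p = 0.315). Light signalling fell in 16 and rose in 8 of 27 (24 adjusted over the list alone; adjusted p = 0.0719), including BBX32 (-3.36±0.27), a light repressor. None of 16 root hair genes passed (adjusted p = 0.909). Root-specific markers rose in 1 and fell in 2 of 18 (3 adjusted over the list alone; adjusted p = 0.880).

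Most temperature calls of Col-0 recurred in the mutants in the same direction. In roots, 79.8% of the Col-0 calls recurred in hy5 and 81.0% in phyAB, and in shoots 85.2% in the libraries labelled hy5 and 78% in phyAB. Some leading genes recurred: MRN1 (3.97±0.20) and BCAT-2 (3.46±0.28) rose in hy5 roots, and MRN1 (4.59±0.24) and BCAT-2 (4.25±0.29) rose in phyAB roots. NRT2.1 fell by 7.16±0.43 in hy5 and 5.54±0.26 in phyAB roots, where CHS joined the largest falls. The temperature effect comprised 12021 genes in hy5 roots (5421 rose, 6600 fell) and 12519 in phyAB roots (6304 rose, 6215 fell), n = 3 per group.

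In hy5 roots, CHS fell from 40.7±6.52 to 0.122±0.0794 CPM (-8.34±0.21, adjusted p = 6.88e-17). All 10 flavonoid genes past the threshold fell, of 11 tested (10 adjusted over the list alone; median -3.09, adjusted p = 3.74e-21, and 0.00446 with an estimated correlation), with FLS1 (-5.81±0.27) and CHI (-3.92±0.21). HYH fell as well (-2.44±0.17, adjusted p = 8.40e-11). Iron genes fell in 20 of 21 (20 adjusted over the list alone; median -1.33, adjusted p = 8.19e-17, but adjusted p = 0.0513 with an estimated correlation), including the nicotianamine synthase NAS4 (-3.36±0.17). Evening clock genes rose in 9 and fell in 1 (10 adjusted over the list alone; adjusted p = 1.36e-05, but adjusted p = 0.0883 with an estimated correlation). The morning gene CCA1 (-4.22±0.52) fell. Phosphate genes fell in 11 of 18 (13 adjusted over the list alone; adjusted p = 0.000173, but adjusted p = 0.322 with an estimated correlation), led by the non-coding starvation transcript IPS1 (-4.20±0.23). Root-specific markers rose in 13 and fell in 3 of 21 (16 adjusted over the list alone; adjusted p = 0.000812, but adjusted p = 0.307 with an estimated correlation). PHYA rose (0.52±0.05), PHYB fell (-0.27±0.05), and HY5 (-0.13±0.08, adjusted p = 0.167), YUC8 (0.27±0.13, adjusted p = 0.0898) and IAA29 (0.65±0.32, adjusted p = 0.0868) did not pass.

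In phyAB roots, CHS fell from 84.4±6.89 to 2±0.260 CPM (-5.38±0.12, adjusted p = 8.55e-18). Flavonoid genes fell in 10 of 11 (10 adjusted over the list alone; median -1.60, adjusted p = 1.81e-17, and 0.00583 with an estimated correlation), with the hydroxylase F3H (-4.74±0.22), CHI (-4.50±0.19) and FLS1 (-3.87±0.14). Root hair genes fell in 17 of 18 (17 adjusted over the list alone; median -1.04, adjusted p = 1.77e-05, but adjusted p = 0.495 with an estimated correlation), such as the expansin EXPA7 (-1.24±0.12) and the wall gene COBL9 (-1.18±0.12). Iron genes fell in 18 of 21 (18 adjusted over the list alone; median -1.16, adjusted p = 2.78e-06, but adjusted p = 0.311 with an estimated correlation). Evening clock genes rose in 9 of 10 (9 adjusted over the list alone; adjusted p = 1.07e-06, but adjusted p = 0.0674 with an estimated correlation). HYH (-1.51±0.11, adjusted p = 8.87e-11) and PHYA (-0.27±0.06, adjusted p = 0.000565) fell, IAA29 rose (0.74±0.23, adjusted p = 0.00920), and HY5 (-0.09±0.08, adjusted p = 0.318), PHYB (-0.08±0.05, adjusted p = 0.188) and YUC8 (0.13±0.14, adjusted p = 0.434) did not pass.

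In the shoot libraries labelled hy5, 6576 genes rose and 5665 fell at 27 °C, n = 3 per group. Flavonoid genes fell in 19 of 20 (19 adjusted over the list alone; median -4.41, adjusted p = 2.00e-42, and 0.00277 with an estimated correlation), CHS to 13.2±1.44 against 617±54.4 CPM (-5.54±0.09, adjusted p = 8.01e-20), with TT19 (-6.24±0.28) and FLS1 (-4.58±0.10). ELIP1 (-8.47±0.70) and ELIP2 (-6.57±0.37) fell, and HY5 itself fell (-1.46±0.12, adjusted p = 1.42e-09), as did HYH (-2.39±0.24, adjusted p = 1.20e-06). PIF4 rose (3.93±0.41, adjusted p = 3.15e-08), YUC8 fell (-0.77±0.17, adjusted p = 0.000570) and IAA29 did not pass (-0.18±0.24, adjusted p = 0.547). Chlorophyll synthesis fell in 14 of 17 (15 adjusted over the list alone; adjusted p = 4.64e-07, but adjusted p = 0.167 with an estimated correlation), including PORC (-1.58±0.06). The hormone transporter ABCG40 (3.88±1.02, adjusted p = 0.00534) and PHYA (0.98±0.08) rose, and PHYB (-0.34±0.06) and NRT2.1 (-3.68±0.35) fell.

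In phyAB shoots, 6079 genes rose and 6050 fell. IAA29, an auxin-response repressor, rose to 12.3±1.99 against 3.68±0.613 CPM (1.74±0.16, adjusted p = 6.85e-09), and YUC8 rose to 6.13±0.760 against 4.47±0.238 CPM (0.46±0.15, adjusted p = 0.00936). PIF and shade genes rose in 19 and fell in 3 of 24 (22 adjusted over the list alone; median 0.97, adjusted p = 2.55e-05, but adjusted p = 0.0866 with an estimated correlation), such as the wall enzyme XTH15 (2.32±0.11) and the homeobox factor ATHB2 (1.74±0.12). Auxin response rose in 15 and fell in 4 of 26 (20 adjusted over the list alone; adjusted p = 0.0515), including IAA19 (1.43±0.15). Flavonoid genes fell in 18 of 20 and 1 rose (19 adjusted over the list alone; median -4.19, adjusted p = 2.45e-44, and 0.00209 with an estimated correlation), with DFR (-7.54±0.49), UGT79B1 (-7.95±0.79), TT19 (-7.29±0.34) and CHS (-5.03±0.09). BCAT-2 (3.60±0.22), PHYA (1±0.10) and PIF4 (1.92±0.49, adjusted p = 0.00198) rose, HY5 (-0.43±0.12), HYH (-0.60±0.21) and NRT2.1 (-3.40±0.28) fell, and PHYB did not pass (0.03±0.06, adjusted p = 0.700). Photosynthesis fell in 30 of 33 (31 adjusted over the list alone; adjusted p = 2.44e-07, but adjusted p = 0.470 with an estimated correlation).

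**Figure D2:**
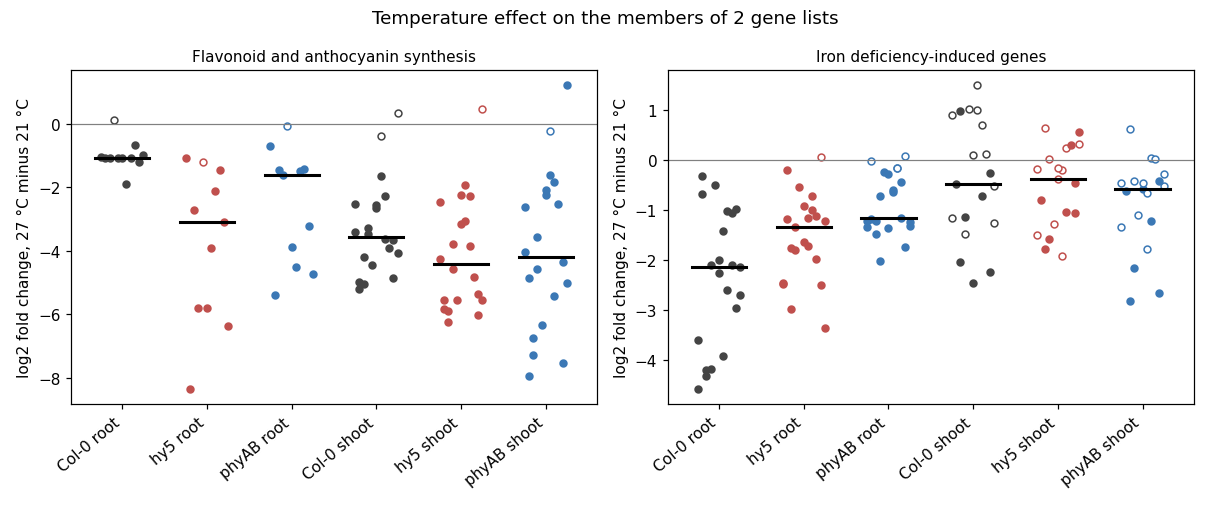
Log2 fold change from 21 to 27 °C (vertical axis) of each member of the flavonoid and iron lists in the temperature effects of roots and shoots of Col-0, hy5 and phyAB, with filled points past the threshold, open points not past it and a line at the median. The flavonoid medians in roots ran from -1.07 in Col-0 to -3.09 in hy5, and the iron medians from -2.13 in Col-0 to -1.16 in phyAB.

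The temperature response of hy5 roots differed from that of Col-0 roots in flavonoid, touch and heat shock genes, among others. CHS fell by 8.34±0.21 in hy5 roots and fell by 1.08±0.08 in Col-0 roots, a difference of -7.26±0.26, adjusted p = 1.01e-13 (n = 3 per group). MYB12, the flavonol regulator, kept 25.6 CPM at 27 °C against 23.7 CPM at 21 °C in Col-0 roots but went from 1.14 to 0.0123 CPM in hy5 (-5.90±0.56, adjusted p = 4.56e-07). The iron transporter IRT1 fell less in hy5, to 376±41.2 from 1240.4 CPM, than in Col-0, to 60.5±15.8 from 916 CPM (2.2±0.22, adjusted p = 2.38e-05). The difference passed in 1486 genes, 423 higher and 1063 lower in hy5. By estimate 661 were larger there, 281 smaller and 544 opposite, but only 153 genes passed in opposite directions.

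Flavonoid genes had lower responses in 9 of 11 (9 adjusted over the list alone; median -1.89, adjusted p = 2.01e-52, and 0.000159 with an estimated correlation), with F3H (-5.39±0.32) and FLS1 (-4.73±0.32). Touch and wound genes had lower responses in 11 of 17 (13 adjusted over the list alone; median -1.02, adjusted p = 1.27e-19, and 0.0249 with an estimated correlation): the transcription factors ERF5 (-1.23±0.15), WRKY33 (-1.21±0.13) and ERF6 (-1±0.13). Heat shock genes had lower responses in 6 of 28 (10 adjusted over the list alone; median -0.22, adjusted p = 0.00170, and 0.0249 with an estimated correlation), including the repressor HSFB2A (-0.77±0.16), DREB2A (-0.63±0.16) and HSP90.1 (-0.45±0.13). Iron genes went the other way in 9 of 21 (15 adjusted over the list alone; median 0.77, adjusted p = 9.82e-17, but adjusted p = 0.0671 with an estimated correlation), with FRO2 (2.1±0.22), BHLH39 (1.59±0.21), which activates uptake, and NAS1 (1.35±0.17). Cold-responsive genes had lower responses in 6 of 13 (10 adjusted over the list alone; adjusted p = 7.22e-05, but adjusted p = 0.0671 with an estimated correlation), among them the dehydrin ERD10 (-0.69±0.08) and RD29A (-1.08±0.17). The phosphate list (6 lower of 18, 9 adjusted over the list alone; adjusted p = 2.40e-07, but adjusted p = 0.154 with an estimated correlation) included the phosphatase PAP10 (-0.69±0.11). Among single genes, the wall enzyme XTH24 (-2.01±0.20), the oxygenase CYP82C4 (2.56±0.40, adjusted p = 0.00167) and HYH (-2.14±0.19, adjusted p = 2.54e-07) differed, while HY5 (-0.24±0.10, adjusted p = 0.188), PHYA (0.21±0.07, adjusted p = 0.0680), PHYB (-0.17±0.07, adjusted p = 0.157), NRT2.1 (-2.22±1.16, adjusted p = 0.314), YUC8 (0.20±0.18, adjusted p = 0.631) and IAA29 (-0.37±0.46, adjusted p = 0.756) did not pass. The glucosidase DIN2 (4.90±0.96, adjusted p = 0.00798) differed as well, but Col-0 libraries at 21 °C scattered (4.62±3.80 CPM).

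In phyAB roots the iron genes fell less with temperature than in Col-0 roots. FRO2 stood at 279±38.7 CPM at 27 °C against 649.5±68.7 CPM at 21 °C, while in Col-0 roots it stood at 23.2 against 556 CPM (3.35±0.22, adjusted p = 3.17e-07, n = 3 per group). IRT1 differed in the same direction (3.29±0.22, adjusted p = 3.38e-07), with 704±51.6 CPM in phyAB at 27 °C. CHS fell more in phyAB (-4.30±0.15, adjusted p = 6.12e-14). The difference passed in 1581 genes (1022 to 2125 leaving out 1 library, 970 without the 2 with contradictory labels), 811 higher and 770 lower. By estimate 725 were larger, 282 smaller and 574 opposite, but only 134 genes passed as opposite.

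Iron genes had higher responses in 17 of 21 and a lower one in 1 (21 adjusted over the list alone; median 1.21, adjusted p = 4.75e-50, and 0.00277 with an estimated correlation), including BHLH39 (2.43±0.21) and NAS1 (1.99±0.17). Flavonoid genes had lower responses in 7 of 11 (7 adjusted over the list alone; median -1.71, adjusted p = 7.16e-37, and 0.000468 with an estimated correlation), with F3H (-3.77±0.26), FLS1 (-2.79±0.17) and CHI (-2.59±0.23). Nitrate genes had higher responses in 15 of 27 (17 adjusted over the list alone; median 0.43, adjusted p = 9.00e-12, but adjusted p = 0.167 with an estimated correlation), such as the nitrite reductase NIR1 (0.68±0.10) and the glutamate synthase GLT1 (0.56±0.09). Root hair genes had lower responses in 7 of 18 (12 adjusted over the list alone; adjusted p = 2.99e-07, but adjusted p = 0.406 with an estimated correlation), with EXPA7 (-0.98±0.16) and MRH6 (-0.99±0.21). Touch genes had lower ones in 7 of 17 (8 adjusted over the list alone; adjusted p = 5.40e-07, but adjusted p = 0.224 with an estimated correlation), with WRKY33 (-0.88±0.13). The auxin-conjugating enzymes GH3.2 (1.19±0.25) and GH3.3 (-1.11±0.20) differed in opposite directions. Among the largest differences were DIN2 (4.96±0.98, adjusted p = 0.00849), with 4.62±3.80 CPM in Col-0 at 21 °C, and the monooxygenase CYP706A2 (-4.35±1.04, adjusted p = 0.0149). The berberine-bridge enzyme genes AT1G26390 (-4.93±1.16) and AT1G26380 (-4.68±1.16) had lower responses. HYH (-1.22±0.13) and PHYA (-0.58±0.08) had lower responses, while PHYB (0.02±0.07, adjusted p = 0.903), HY5 (-0.20±0.10, adjusted p = 0.234), YUC8 (0.06±0.18, adjusted p = 0.894), IAA29 (-0.29±0.40, adjusted p = 0.723) and NRT2.1 (-0.60±0.89, adjusted p = 0.747) did not pass.

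The shoot libraries labelled hy5 differed from Col-0 shoots in the fewest genes, 138 (81 to 246 leaving out 1 library, 258 with DESeq2), of which 69 had a higher and 69 a lower response. SQN, a cyclophilin of the microRNA pathway, went from 55.2±2.62 to 139±10.3 CPM in them and from 25.6±0.491 to 12.6±0.765 CPM in Col-0 (2.34±0.10, adjusted p = 2.41e-12, n = 3 per group). HY5 itself differed (-1.18±0.16, adjusted p = 0.000618), since it exceeded Col-0 at 21 °C and not at 27 °C. CHS fell more than in Col-0 (-1.47±0.11, adjusted p = 2.64e-07).

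Flavonoid genes had lower responses in 4 of 20 (10 adjusted over the list alone; median -0.84, adjusted p = 1.61e-20, and 0.0207 with an estimated correlation), with F3H (-1.72±0.20) and FLS1 (-1.12±0.13). The extracellular protein genes PELPK1 (2.55±0.25, adjusted p = 0.000128) and PELPK2 (2.36±0.41, adjusted p = 0.00575) had higher responses, and the microRNA precursor MIR163 (-2.53±0.55, adjusted p = 0.0437), ERF6 (-2.07±0.45, adjusted p = 0.0444) and IAA17 (-0.74±0.12) lower ones. LUX had a higher response (0.62±0.11, adjusted p = 0.00657). Touch genes were called as a list with 1 of 17 past the threshold (5 adjusted over the list alone; adjusted p = 1.99e-06, but adjusted p = 0.341 with an estimated correlation). HYH (-1.40±0.32, adjusted p = 0.0863), IAA29 (-0.94±0.40, adjusted p = 0.433), PIF4 (-1.07±0.81, adjusted p = 0.771), YUC8 (-0.36±0.25, adjusted p = 0.709), PHYA (0.05±0.11, adjusted p = 0.946), PHYB (0.01±0.09, adjusted p = 0.985) and NRT2.1 (0.38±0.62, adjusted p = 0.921) did not pass.

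Genes of shade growth, auxin response and wall loosening had higher temperature responses in phyAB shoots than in Col-0 shoots. XTH15, which remodels xyloglucan in walls, responded by 2.32±0.11 in phyAB and by 0.60±0.13 in Col-0 (1.72±0.17, adjusted p = 3.36e-06, n = 3 per group). The auxin-response repressor IAA19 responded by 1.43±0.15 against -0.38±0.21 (1.82±0.26, adjusted p = 0.000156), and YUC8 differed too (0.87±0.23, adjusted p = 0.0191). PIF4 went the other way (-3.07±0.85, adjusted p = 0.0262), on few reads. The difference passed in 1839 genes, 844 higher and 995 lower. By estimate 462 were larger, 773 smaller and 604 opposite, but only 157 genes passed as opposite.

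PIF and shade genes had higher responses in 12 of 24 and lower in 1 (16 adjusted over the list alone; median 0.83, adjusted p = 1.63e-12, and 0.00539 with an estimated correlation), including ATHB2 (1.25±0.19) and the growth factor BEE1 (1.09±0.14). Auxin response had higher ones in 6 of 26 (10 adjusted over the list alone; median 0.54, adjusted p = 1.01e-07, and 0.00402 with an estimated correlation), such as IAA7 (0.63±0.07) and IAA17 (0.69±0.12). Cell wall loosening had higher ones in 9 of 26 (12 adjusted over the list alone; median 0.33, adjusted p = 6.18e-10, and 0.0249 with an estimated correlation), with the expansin EXPA11 (1.17±0.10) and the wall enzymes XTH17 (1.56±0.23) and XTH8 (1.08±0.11). Photosynthesis had lower responses in 4 and higher in 1 of 33 (5 adjusted over the list alone; adjusted p = 0.134), with the antenna genes LHCB3 (-1.55±0.23), LHCA4 (-1.28±0.16) and LHCB1.2 (-1.26±0.17) lower. PHYB (0.39±0.09) and CHS (-0.96±0.11) differed modestly, while IAA29 (0.98±0.38, adjusted p = 0.111), HY5 (-0.15±0.16, adjusted p = 0.650), HYH (0.38±0.30, adjusted p = 0.507), PHYA (0.06±0.13, adjusted p = 0.830) and NRT2.1 (0.67±0.52, adjusted p = 0.544) did not pass. The 3 largest differences per direction among genes with a mean CPM of at least 2 follow. Lower were the seed vacuole channel BETA-TIP (-5.26±0.81, adjusted p = 0.000644), the germin-like GLP9 (-3.84±0.64, adjusted p = 0.00193) and the defence protein ACD6 (-3.12±0.43, adjusted p = 0.000816). Higher were the unnamed AT4G35720 (3.23±0.34), the glycosyltransferase UGT73C1 (2.73±0.63, adjusted p = 0.0159) and the unnamed AT3G24460 (2.35±0.41). Transcripts of other organs also differed between the temperatures in phyAB shoots: 13 seed genes summed to 1189 CPM at 21 °C and 240.0 CPM at 27 °C, and root-specific markers to 120 and 207 CPM, against 76.7 and 78 CPM in Col-0.

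**Figure D3:**
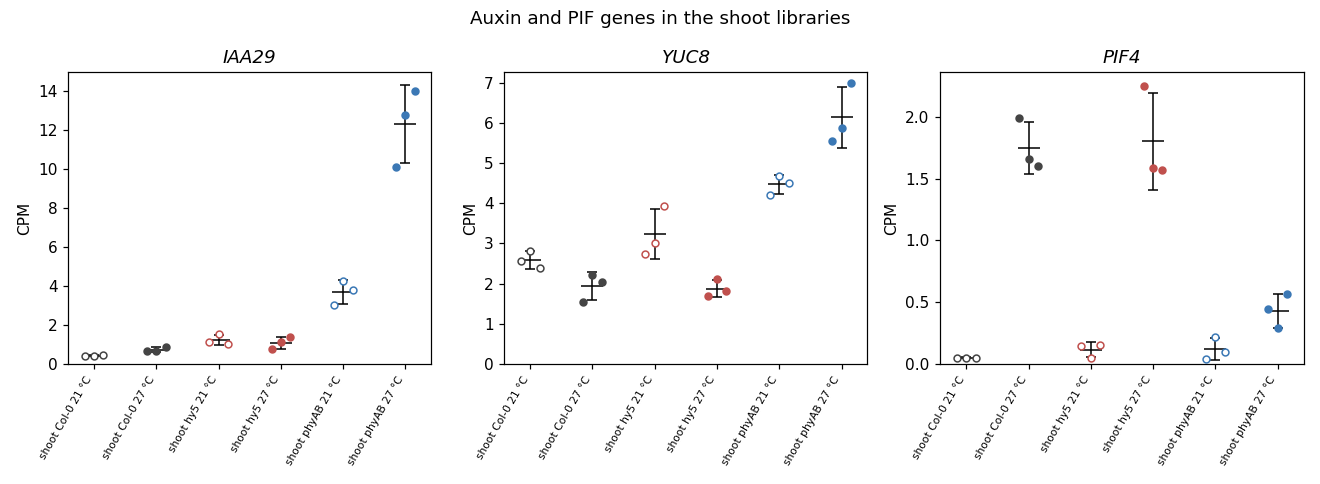
CPM of IAA29, YUC8 and PIF4 (vertical axes) in each shoot library of Col-0, hy5 (as labelled) and phyAB, with open points at 21 °C, filled points at 27 °C, dashes for means and bars for standard deviations (n = 3). IAA29 averaged 3.68 CPM at 21 °C and 12.3 CPM at 27 °C in phyAB, against 0.428 and 0.732 CPM in Col-0.

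Between tissues of Col-0, flavonoid genes fell less at 27 °C in roots than in shoots. CHS responded by -1.07±0.08 in roots and -4.16±0.09 in shoots (root minus shoot 3.09±0.12, adjusted p = 2.49e-19, n = 3 per group). FRO2 responded by -4.56±0.24 and -1.22±0.40 (-3.34±0.50, adjusted p = 7.75e-06). NIA1, which reduces nitrate, responded lower in roots than in shoots (-3.06±0.15, adjusted p = 2.42e-15). Of 21872 genes tested over both tissues, 4466 had a higher and 2883 a lower response in roots. Across 19264 genes tested in each tissue alone, 6444 changed in the same direction (3302 up, 3142 down), where independent calls would give 1676 and 1502, and 910 changed in opposite directions.

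Flavonoid genes responded higher in roots in 13 of 20 (13 adjusted over the list alone; median 2.62, adjusted p = 2.35e-19, and 0.00539 with an estimated correlation), with FLS1 (2.47±0.11), CHIL (2.43±0.14) and 4CL3 (2.32±0.13). Chlorophyll synthesis did so in 15 of 17 (15 adjusted over the list alone; median 1, adjusted p = 3.80e-12, and 0.00760 with an estimated correlation), including the first committed enzyme HEMA1 (1.79±0.14) and CHLI1 (0.90±0.09). Photosynthesis followed in 19 of 33 (21 adjusted over the list alone; adjusted p = 1.89e-08, but adjusted p = 0.429 with an estimated correlation), with PSBO2 (2.29±0.11). Heat shock followed in 18 of 30 (19 adjusted over the list alone; adjusted p = 0.00147, but adjusted p = 0.0866 with an estimated correlation), with CLPB3 (1.13±0.09) and HSP70 (1.22±0.18). Iron genes responded lower in roots in 16 of 21 (16 adjusted over the list alone; median -1.52, adjusted p = 5.17e-07, but adjusted p = 0.239 with an estimated correlation), including MYB10 (-3.82±0.31) and the regulators BHLH38 (-4.54±0.85, adjusted p = 0.000129) and BHLH100 (-5.62±1.18, adjusted p = 0.000512). BHLH100 scattered in shoots, with 24.4±20.7 CPM at 27 °C. The peroxidase GPX7 (4.92±0.73, adjusted p = 3.39e-06) and the transporter ABCG40 (-4.85±1.8, adjusted p = 0.0396) were among the largest differences. MYB111, a flavonol regulator, went from 27.6 to 4.18 CPM in shoots and had no reads in roots at 21 °C. Among the light genes, HY5 (0.49±0.13), HYH (0.79±0.23) and PHYB (0.35±0.08) responded higher in roots, PHYA (-0.53±0.09) lower, and YUC8 (0.58±0.21) higher, while IAA29 (0.35±0.46, adjusted p = 0.640) and NRT2.1 (-0.76±0.86, adjusted p = 0.556) did not pass. PIF4 had no reads in Col-0 roots.

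In hy5 roots flavonoid transcripts were far below those of Col-0, and transcripts of chlorophyll synthesis, light signalling and cold response were lower too. CHS stood at 0.122 CPM at 27 °C and 40.7 CPM at 21 °C in hy5 roots against 457 and 967 CPM in Col-0 (-8.20±0.10, adjusted p = 8.16e-25, n = 3 per group, mean of both temperatures). FLS1 (-7.75±0.09) and HYH, the relative of HY5 (-3.81±0.08), were lower as well. So was CHLH (-5.35±0.09, adjusted p = 2.46e-23), a chelatase subunit of chlorophyll synthesis. Of 20550 genes tested, 6333 were higher and 5845 lower in hy5, 801 and 1152 of them by 2-fold or more.

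All 11 flavonoid genes were lower in hy5 roots (11 adjusted over the list alone; median -5.37, adjusted p = 2.15e-115, and 3.33e-05 with an estimated correlation), with CHI (-6.07±0.07) and the glycosyltransferase UGT78D2 (-3.90±0.07). Chlorophyll synthesis was lower in 14 of 17 (14 adjusted over the list alone; median -0.73, adjusted p = 3.29e-16, and 0.00539 with an estimated correlation), including the synthase CHLG (-4.92±0.12) and the reductase PORB (-4.71±0.16). Light signalling was lower in 22 and higher in 2 of 26 (24 adjusted over the list alone; median -0.79, adjusted p = 6.21e-21, and 0.00660 with an estimated correlation): HFR1 (-5.36±0.13), the repressors SPA4 (-4.32±0.10) and RUP1 (-4.21±0.13), and BBX20 (-2.02±0.05). Cold-responsive genes were lower in 11 of 13 (13 adjusted over the list alone; median -2.30, adjusted p = 8.49e-32, and 0.000159 with an estimated correlation), with the protective proteins RD29A (-4.14±0.07) and COR47 (-2.30±0.04). KIN2 (-5.28±0.09) was lower, and its reads may be shared with KIN1. Photosynthesis was lower in 28 of 31 (28 adjusted over the list alone; adjusted p = 5.51e-14, but adjusted p = 0.290 with an estimated correlation), with PSBO2 (-3.77±0.09). Its summed CPM in hy5 roots was 60.5±11.4 at 21 °C against 343±62.9 in Col-0.

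Higher in hy5 roots were genes of salicylic acid defence, in 11 of 16 (12 adjusted over the list alone; median 1.25, adjusted p = 1.14e-05, but adjusted p = 0.113 with an estimated correlation), among them the enzymes ALD1 (3.52±0.12, adjusted p = 6.41e-17) and FMO1 (3.77±0.19) of the pipecolate defence pathway. Iron genes were higher in 15 of 21 (17 adjusted over the list alone; adjusted p = 0.000133, but adjusted p = 0.430 with an estimated correlation), with FRO2 (1.57±0.11) and IRT1 (1.54±0.11). Touch genes were higher in 13 of 17 (14 adjusted over the list alone; adjusted p = 0.00149, but adjusted p = 0.475 with an estimated correlation). MRN1 (3.48±0.21), the starvation transcript IPS1 (2.85±0.26) and the clock gene GI (2.52±0.21) were higher, and ELF4 (-1.72±0.09), the root hair gene PRP1 (-2.96±0.16) and DREB2A (-1.46±0.08) lower. The lipid enzyme FADA had 0.138 CPM in hy5 at 21 °C against 17.3 CPM in Col-0 and no reads in hy5 at 27 °C. PHYA (-0.24±0.03), PHYB (-0.58±0.03) and YUC8 (-0.46±0.09) were lower, and IAA29 (0.08±0.23, adjusted p = 0.810) and NRT2.1 (-0.04±0.33, adjusted p = 0.925) did not pass. Some genes without symbols went from few or no reads to many, such as AT2G03965 with 366±12.8 CPM in hy5 at 21 °C against 0.0829 CPM in Col-0.

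In phyAB roots the same groups were lower as in hy5 roots. CHS was lower (-5.67±0.07, adjusted p = 7.82e-24, n = 3 per group, mean of both temperatures), as was the flavonoid hydroxylase gene F3'H (-6.59±0.11). The glucosyltransferase UGT84A2 (-6.09±0.08, adjusted p = 1.76e-24) was low as well. MRD1, a gene of unknown biochemistry, was higher, at 42.6±1.37 CPM in phyAB at 21 °C against 0.149 CPM in Col-0 (8.79±0.11, adjusted p = 5.26e-25). Of 20550 genes tested, 5406 were higher and 5096 lower, 787 and 1020 of them by 2-fold or more.

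All 11 flavonoid genes were lower in phyAB roots (11 adjusted over the list alone; median -5.12, adjusted p = 8.64e-136, and 2.31e-06 with an estimated correlation), including CHI (-5.84±0.07) and FLS1 (-5.45±0.07). Chlorophyll synthesis was lower in 15 of 17 (15 adjusted over the list alone; median -0.73, adjusted p = 4.43e-17, and 0.00512 with an estimated correlation), with CHLH (-3.89±0.07), PORB (-4.50±0.15) and CHLG (-3.75±0.10). Light signalling, a list that includes PHYA and PHYB, was lower in 19 of 26 (23 adjusted over the list alone; median -1.24, adjusted p = 6.07e-31, and 0.00201 with an estimated correlation), with ELIP2 (-4.17±0.10) and SPA4 (-2.94±0.09). Cold-responsive genes were lower in 11 of 13 (12 adjusted over the list alone; median -1.77, adjusted p = 1.30e-35, and 8.16e-05 with an estimated correlation), with RD29A (-4.17±0.07) and COR47 (-1.77±0.04). KIN1 (-6.21±0.18) and KIN2 (-7.18±0.11) were lower too, on reads that may be shared. Photosynthesis was lower in 25 of 31 (25 adjusted over the list alone; adjusted p = 1.53e-11, but adjusted p = 0.322 with an estimated correlation), with PSBO2 (-3.41±0.08). Its summed CPM was 65.8±4.57 at 21 °C and 118±69.5 at 27 °C. HYH (-1.93±0.07) and HFR1 (-3.12±0.10) were lower.

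Iron genes were higher in 18 of 21 (19 adjusted over the list alone; median 1.16, adjusted p = 3.37e-11, but adjusted p = 0.153 with an estimated correlation), including the regulators BHLH39 (1.97±0.10) and FIT (0.91±0.06) and the coumarin exporter PDR9 (0.87±0.05). Salicylic acid defence was higher in 11 of 16 (13 adjusted over the list alone; median 1.38, adjusted p = 1.56e-06, but adjusted p = 0.0801 with an estimated correlation), with FMO1 (3.47±0.20) and ALD1 (3.23±0.12). Root-specific markers were higher in 17 of 21 (18 adjusted over the list alone; adjusted p = 2.55e-05, but adjusted p = 0.167 with an estimated correlation), with TIP2;3 (1.88±0.06). Root hair genes included RSL4 (-1.88±0.09), the growth regulator, and PRP1 (-3.52±0.17), both lower. The lectin PP2-A6 (4.72±0.10, adjusted p = 9.04e-19), NRT2.1 (2.06±0.35, adjusted p = 6.15e-05) and IAA29 (1.37±0.20, adjusted p = 3.14e-06) were higher, and YUC8 (-0.60±0.09) lower.

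The shoot libraries labelled hy5 held fewer flavonoid transcripts and more root-specific marker transcripts than Col-0 shoots. CHS was lower (-1.38±0.06, adjusted p = 1.76e-13, n = 3 per group, mean of both temperatures), by far less than in roots. GASA5, a gibberellin-regulated peptide gene, was lower (-4.39±0.23, adjusted p = 6.99e-12), and CSLA03, a mannan synthase, stood at 1.48 CPM against 29.9 CPM in Col-0 at 21 °C (-4.18±0.09, adjusted p = 7.20e-19). Of 20574 genes tested, 2976 were higher and 3251 lower, 750 and 249 of them by 2-fold or more.

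Flavonoid genes were lower in 17 of 20 (17 adjusted over the list alone; median -1.02, adjusted p = 8.56e-24, and 0.00986 with an estimated correlation), with FLS1 (-1.74±0.06) and F3H (-1.67±0.10), and HYH (-0.81±0.16) was lower. Root-specific markers were higher in 13 of 18 (14 adjusted over the list alone; median 1.37, adjusted p = 2.11e-09, and 0.0368 with an estimated correlation), with the endodermal CASP2 (2.39±0.24), whose reads may be shared with its relatives, and the triterpene oxidase MRO (2.57±0.28). Their summed CPM was 96.9±5.24 at 21 °C and 138±10.1 at 27 °C, against 76.7±6.47 and 78±4.58 in Col-0 shoots and 1006±109 in Col-0 roots at 21 °C. Root hair genes were higher in 11 of 16 (15 adjusted over the list alone; median 1.28, adjusted p = 0.000353, but adjusted p = 0.498 with an estimated correlation), such as the oxidase RHD2 (1.11±0.20). Touch genes were higher in 15 of 17 (15 adjusted over the list alone; median 1.21, adjusted p = 3.37e-11, but adjusted p = 0.167 with an estimated correlation), including the wall enzyme TCH4 (1.21±0.11) and ERF6 (1.84±0.22). Salicylic acid defence was higher in 10 of 16 (14 adjusted over the list alone; median 1.49, adjusted p = 5.62e-06, but adjusted p = 0.322 with an estimated correlation), with the regulators CBP60G (2.07±0.25) and WRKY54 (2.17±0.35). Light signalling was lower in 13 of 27 (16 adjusted over the list alone; adjusted p = 4.01e-05, but adjusted p = 0.153 with an estimated correlation), with RUP1 (-1.16±0.09) and BBX30 (-1.70±0.27). IAA29 was higher (1.05±0.20, adjusted p = 0.000383), and YUC8 (0.13±0.12, adjusted p = 0.459), PIF4 (0.58±0.41, adjusted p = 0.351), PHYA (-0.11±0.06, adjusted p = 0.180), PHYB (-0.08±0.04, adjusted p = 0.155) and NRT2.1 (-0.04±0.34, adjusted p = 0.960) did not pass. KIN1 was lower (-3.11±0.26, adjusted p = 2.41e-07), and AT2G03965 again went from 0.0668 CPM in Col-0 to 532±19.7 CPM at 21 °C.

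In phyAB shoots, genes of shade growth and auxin response were higher, as were seed storage genes. IAA29 stood at 3.68±0.613 CPM at 21 °C and 12.3±1.99 CPM at 27 °C against 0.428 and 0.732 CPM in Col-0 (3.57±0.16, adjusted p = 2.87e-13, n = 3 per group, mean of both temperatures). Also higher were PIL1, an early shade marker (3.87±0.22, adjusted p = 1.78e-11), the light-signalling factor HFR1 (3.03±0.12, adjusted p = 6.33e-14) and the expansin EXPA8 (2.09±0.05, adjusted p = 5.94e-17). Of 20574 genes tested, 4492 were higher and 5368 lower, 1057 and 187 of them by 2-fold or more.

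PIF and shade genes were higher in 21 of 24 (23 adjusted over the list alone; median 1.19, adjusted p = 7.26e-20, and 0.000918 with an estimated correlation). Auxin response was higher in 19 of 26 (23 adjusted over the list alone; median 0.82, adjusted p = 3.85e-11, and 0.00166 with an estimated correlation), with IAA19 (1.97±0.13), IAA7 (0.89±0.03) and IAA3 (0.65±0.05). Auxin synthesis and transport was higher in 10 of 17 (12 adjusted over the list alone; median 0.38, adjusted p = 1.47e-05, and 0.00650 with an estimated correlation), with YUC8 (1.22±0.11, adjusted p = 1.54e-08), the importer AUX1 (0.61±0.03) and the exporter PIN7 (0.89±0.05). Cell wall loosening was higher in 14 of 26 (15 adjusted over the list alone; median 0.51, adjusted p = 4.64e-07, but adjusted p = 0.0674 with an estimated correlation), with XTH17 (2.27±0.11) and EXPA3 (1.11±0.04). Photosynthesis was lower in 31 of 33 (31 adjusted over the list alone; median -0.58, adjusted p = 1.30e-35, but adjusted p = 0.0502 with an estimated correlation), among them LHCA3 (-0.91±0.05) and PSAE1 (-0.79±0.04). Flavonoid genes were lower in 17 of 20 (17 adjusted over the list alone; median -0.80, adjusted p = 3.09e-09, but adjusted p = 0.142 with an estimated correlation), with CHS (-0.75±0.05) and FLS1 (-1.23±0.06). Chlorophyll synthesis was lower in 14 of 17 (14 adjusted over the list alone; adjusted p = 1.11e-08, but adjusted p = 0.113 with an estimated correlation), with PORC (-0.54±0.04).

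Transcripts of other organs moved with phyAB shoots. The seed storage genes CRA1 (8.57±0.53, adjusted p = 2.86e-08), at 518±148 CPM in phyAB at 21 °C against 0.982 CPM in Col-0, CRU3 (10.27±0.61, adjusted p = 1.90e-08) and M17 (7.05±0.58, adjusted p = 4.38e-07) were among the largest increases. The seed protein genes ATECP31 and EM1 stood at 12.8 and 10.5 CPM in phyAB at 21 °C and had no reads in Col-0 at 21 °C and at 27 °C, respectively. The summed CPM of 13 seed genes was 1189±364 at 21 °C and 240.0±128 at 27 °C in phyAB shoots, against 4.09 and 1.72 in Col-0 shoots. Root-specific markers were higher in 11 of 18 (12 adjusted over the list alone; median 1.37, adjusted p = 3.89e-11, and 0.0249 with an estimated correlation), with the Casparian strip genes CASP2 (4.2±0.20) and CASP1 (3.28±0.17). Their summed CPM was 120±8.17 at 21 °C and 207±24.8 at 27 °C, against 76.7±6.47 and 78±4.58 in Col-0 shoots. Salicylic acid defence was higher in 11 of 16 (12 adjusted over the list alone; adjusted p = 0.000135, but adjusted p = 0.430 with an estimated correlation), with the glucanase PR2 (5.79±0.78). Lower were GASA5 (-3.05±0.18, adjusted p = 3.13e-11), UGT79B1 (-2.84±0.67, adjusted p = 0.00323) and KIN1 (-2.90±0.26), whose reads may be shared with KIN2. HYH (0.07±0.15, adjusted p = 0.735) and PIF4 (-0.43±0.52, adjusted p = 0.577) did not pass, and NRT2.1 was higher (0.84±0.26, adjusted p = 0.0147).

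The genotype calls of hy5 and phyAB overlapped in roots, where 7580 genes changed in the same direction, 3683 up and 3897 down, and 453 in opposite directions, against 1666 and 1449 for independent calls. CHS, FLS1, CHLH and RD29A were lower in both mutants, and FMO1 and ALD1 higher. In shoots, 3212 genes changed in the same direction in the libraries labelled hy5 and in phyAB, 1425 up and 1787 down, and 711 in opposite directions, against 649.8 and 848 for independent calls. CHS was lower in both, CASP2 higher in both, and IAA29 higher in both. Both mutants were compared with the same 3 Col-0 libraries per temperature, so the 6 libraries of each tissue were also divided between the mutants in 18 ways, with none used for both. Shared calls then numbered 5748 to 6247 in roots and 1625 to 2037 in shoots, at least 2.60 and 2.29 times those of independent calls. In 20 simulations per tissue with shared controls and no effects, none gave a shared call, but they called a median of 0 genes. Simulated folds hardly correlated (median r 0.0451 in roots, 0.0383 in shoots), so the simulations do not speak against shared controls. The covariance of the real folds was 0.540 and 0.190.

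Over the 15 comparisons, 143 of 330 list tests passed at the preset correlation. Within tissues, regrouped libraries gave a median of 117 such calls against 134 as labelled, so calls at the preset correlation alone are weak evidence. With an estimated correlation 32 passed. The flavonoid list held in all 6 temperature effects, in the differences of hy5 and phyAB roots and of the shoot libraries labelled hy5 from Col-0, between tissues, and in all genotype effects but that of phyAB shoots. The iron list held in Col-0 roots and in the phyAB root difference, and the touch and heat shock lists in the hy5 root difference. The others that held were the chlorophyll, light signalling and cold lists in the genotype effects of both mutant roots, chlorophyll between tissues, root-specific markers in both mutant shoots, auxin response and the PIF and shade list in phyAB shoots by genotype and by temperature difference, auxin synthesis in the former, and cell wall loosening in the latter.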

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

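The regrouping tests of single comparisons and the tests of the hy5 shoot label, of seed genes, of on or off genes, of the control libraries shared by both mutants and of the size of the root marker rise were chosen only after the results were seen, and those of the phyAB root labels, the calls shared by both mutants, the gene lists and the direction of the root markers before.

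The temperature response differed between hy5 and Col-0 roots in 1486 genes by the interaction test. The log2 differences named were DIN2 4.90, AT5G14650 2.88, CYP82C4 2.56, CHS -7.26, MYB12 -5.90 and HYH -2.14, and AT2G08650 -6.35, which had no reads in hy5 at 27 °C and whose value is no bound. List medians differed by -0.22 for heat shock, -1.89 for flavonoid and -1.02 for touch genes. Of 100 regroupings the highest other gave 915 calls, keeping the labelled groups of 1 genotype. These regroupings mixed temperatures within a genotype, so chance was not excluded.

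Between phyAB and Col-0 roots the response differed in 1581 genes, by the same test: DIN2 4.96, FRO2 3.35, IRT1 3.29, AT1G26390 -4.93, AT1G26380 -4.68, CYP706A2 -4.35, HYH -1.22, PHYA -0.58 and CHS -4.30. The list medians differed by -1.71 for flavonoid and 1.21 for iron genes. Another regrouping of 100 gave 1972 calls, keeping the labelled groups of 1 genotype, and for the same reason chance was not excluded.

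The shoot libraries labelled hy5 differed from Col-0 in 138 genes: PELPK1 2.55, PELPK2 2.36, SQN 2.34, MIR163 -2.53, ERF6 -2.07, AT2G08650 -2.01, HY5 -1.18 and CHS -1.47, with a flavonoid median of -0.84. The highest other regrouping of 100 gave 9 calls, and again chance was not excluded.

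In phyAB shoots 1839 genes differed: AT4G35720 3.23, UGT73C1 2.73, AT3G24460 2.35, BETA-TIP -5.26, GLP9 -3.84, ACD6 -3.12, PHYB 0.39, PIF4 -3.07, YUC8 0.87 and CHS -0.96. List medians differed by 0.54 for auxin response, 0.83 for PIF and shade and 0.33 for cell wall genes. The highest other regrouping of 100 gave 445 calls, and chance was not excluded.

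Between Col-0 tissues 7349 genes differed: AT1G52342 5.003, GPX7 4.92, BHLH100 -5.62, ABCG40 -4.85, BHLH38 -4.54, HY5 0.49, HYH 0.79, PHYA -0.53, PHYB 0.35, YUC8 0.58 and CHS 3.09, and MYB111 6.13, which had no reads in roots at 21 °C and whose value is no bound. List medians differed by 2.62 for flavonoid and 0.9995 for chlorophyll genes. The highest other regrouping of 100 gave 6942 calls, and chance was not excluded.

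For the temperature effects, the labelled grouping was the only 1 of 10 splits with as many calls in each tissue and genotype, with at most 1 call in any other split, and 10 splits are too few for a share under 0.05. For the genotype effects the highest other counts were 6455 and 5762 in hy5 and phyAB roots and 2059 and 4409 in shoots, each 1 of 100, so chance can be excluded. Calls shared by both mutants reached 7309 in other regroupings of roots, against 7580 as labelled, and 2095 of shoots, against 3212, each 1 of 100. These regroupings redrew the genotypes of all libraries. They speak for an effect of genotype but do not test whether the overlap exceeds that of independent effects. With the Col-0 libraries divided between the mutants, shared calls were at least 2.60 times those of independent calls in roots and 2.29 times in shoots, so shared control libraries are excluded as the whole cause, and a trait common to all Col-0 libraries was not tested. Within tissues 134 list tests passed, and 8 of 60 regroupings gave as many, up to 146. The median of the other regroupings was 117, so chance cannot be excluded for the number of list calls at the preset correlation. With an estimated correlation 31 passed, against at most 2 in the other regroupings.

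The phyAB root replicate 3 libraries, whose source label says shoot, had at most 71.0 CPM over the photosynthesis list, against 68085 in the lowest shoot library, so a mislabelled tissue was excluded. The 21 °C shoot libraries labelled hy5 lay nearer to their 27 °C group than to Col-0 shoots (highest distance ratio 0.652 over 165 genes), so an exchange with Col-0 was excluded, and the HY5 transcript level remained unexplained.

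The 13 seed genes, all higher in phyAB shoots, fell from 21 to 27 °C with a distance of 0.757 between the quartiles of their log2 changes, though these ran from -3.46±0.48 for SESA4 to -1.08±0.35 for EM1, around a median of -2.57. Ungerminated seeds or seed remnants in the phyAB shoot samples, more at 21 °C, remain a candidate cause, but EM1 fell less than 1 fixed seed profile would give. Depth does not account for it, since library sizes overlapped. A change of seed genes inside seedlings could also give such a fall, and no biological explanation was tested.

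Root-specific markers, higher in shoots of both mutants, might come from root tissue there. Of 22 abundant root genes, 95.5% were higher in each mutant, as predicted beforehand for root tissue. Only 14 passed in hy5 and 4 in phyAB, all higher, so this cannot decide. A test of size was added after that result, and its reference, marker set and bounds were revised once its values were seen: against Col-0 roots hy5 stayed undecided and phyAB gave the same verdict, and roots of the same genotype replaced them. The 18 markers exceeded Col-0 shoots by a median of 1.99% of that root level in the libraries labelled hy5 and 3.77% in phyAB (lower quartile 0.839%), the abundant root genes by 1.67% (upper quartile 2.15%) and 0.294% (upper quartile 0.429%). In phyAB this argues against whole-root tissue as the sole cause, but root tissue remains a candidate in both beside an effect of the mutation.

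In hy5, 34 genes were on or off by at least 16-fold in both tissues, 29 higher and 5 lower, and 9 genes in phyAB. A strain variant might account for them if they clustered: at most 4 of the 34 lay in a run of 200 neighbouring genes (p = 0.0333 by permutation), and none within 200 genes of HY5. In phyAB at most 2 lay together (p = 0.350 by permutation), which cannot tell. For hy5 a strain variant therefore remains a candidate, without excluding an effect of the mutation. Reads mapped to a wrong copy were not tested for these genes.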

How the results depend on the processing

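The leave-one-out and other alternatives were set before the data were examined, except that without the phyAB root replicate 3 libraries, chosen after seeing the data. No result reversed, and the counts of all comparisons kept within 1.5 times their value with RLE size factors, no filter on low counts and only the groups compared. Other settings moved some results further, and the cause was not tested. With DESeq2 the hy5 shoot difference rose to 258 genes. Leaving out 1 library at a time, it ran from 81 to 246, with 81 and 91 without the Col-0 replicate 2 library at 27 or 21 °C and 246 without the hy5 replicate 1 library at 27 °C. The phyAB root difference ran from 1022, without the Col-0 replicate 3 library at 27 °C, to 2125. These counts also rest on fewer samples. Without the 2 libraries with contradictory labels the phyAB root difference passed in 970 genes, 873 of them among those reported. With an estimated correlation 32 of 143 list calls remained. The hy5 root and phyAB shoot differences ran from 1041 to 1436 and from 1287 to 1836 genes, and the counts of the other comparisons and the shared calls also kept within 1.5 times their value. For the lists, 1 replicate number was left out of every group at once, which gave 140 to 157 list calls. Of 1378 named gene results, 14 no longer passed and 7 newly passed with DESeq2, 17 and 2 without a filter and 18 and 2 with only the groups compared. Over all leave-one-out runs 377 named gene results no longer passed and 35 newly passed, beside 12524 with no such change, and 18 no longer passed without the 2 libraries with contradictory labels. Few reads limit PIF4, MYB72 and NRT2.1, and the tests recovered fewer small differences between responses than direct effects.

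Correlations between equal replicate numbers ran from -0.175 to 0.383. Their medians were positive in all 15 comparisons (0.0105 to 0.184) and those between other numbers negative, a hint of something shared by number. Reads outside genes peaked at the same number at both temperatures, except in Col-0 roots. In no comparison did every pair exceed 0.1, so the fits were unpaired, which cannot exclude pairing. With the number as a replicate block, the Col-0 root temperature effect passed in 11237 genes, the phyAB shoot difference in 2404 and the hy5 shoot difference in 203.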

Other observations

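No tests were chosen after the results for the values in this part. MRD1, a gene of unknown biochemistry, was higher in both mutants and both tissues, and AT1G75945 was lower in both, with no reads in hy5 roots at 27 °C against 6.66 CPM in Col-0 roots. In hy5 roots at 27 °C the marneral synthase gene MRN1 reached 141±19.2 CPM, against 13.7±1.44 CPM in Col-0 roots at the same temperature.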
